A study of Mus musculus with 8 samples.

How the data were processed

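Total RNA of epididymal adipose tissue from 105-week-old mice on a C57BL/6 background was purified on silica columns, and libraries were made with an MGIEasy RNA kit and sequenced on a DNBSEQ-G400 instrument, per the labels' protocols. Per the submitters' processing notes, reads were aligned with HISAT2 to mouse build mm39. The HISAT2 version, the counting tool, the gene annotation and the strand setting are not given in the sources used here, nor is the RNA selection or the way the gene was deleted. The authors deposited 1 table of raw counts, whole numbers of reads per Ensembl gene, with 1 column for each of the 8 libraries and 57010 genes. All columns matched a sample by its library name, and 0 were left unmatched. Samples were grouped by the labels' genotype into WT and KO, and each library is named here by group and number as labelled.

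Gene symbols were taken from the GENCODE M21 annotation of assembly GRCm38, which named 52029 (91.263%) of the genes by identifier. Unnamed genes held 0.223% to 0.267% of the counts of a library. Because that assembly differs from the build of the files, it was used only for names, chromosome names and the order of neighbouring genes, and no coordinates are given. Without a stated strand setting, reads of overlapping or antisense genes cannot be separated.

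The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16182 genes. Libraries were scaled by TMM, and a quasi-likelihood model with the group as the only term was fitted to all 8 libraries. Fold changes are KO minus WT on the log2 scale, and the standard error is the size of the fold change divided by the square root of the quasi-likelihood F statistic. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values are TMM-scaled and are given as mean ± SD over 4 libraries. Log2 CPM used a prior count of 2. The common biological coefficient of variation was 27.7%. Fmo3 was also tested with an exact permutation of the group means. The depth per library was 17531632 to 18485177 counts, and 3 counts corresponded to between 0.161 and 0.176 TMM-scaled CPM.

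Choices made before the data were examined were 42 gene lists (878 names, of which 29 were not found), the named-gene rule and the alternatives. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one. The test fry asked instead whether a list's genes moved, on balance, one way, without comparing them with other genes. A list's mean is the mean of its members' log2 fold changes. Named genes were, first, all Fmo genes with counts and, second, up to 10 genes per direction with the largest fold change among those past the threshold, with at least 2 CPM on average and no overlap of the groups, leaving out gene models without an approved symbol. Where fewer than 5 passed in a direction, this was filled to 5 by the smallest unadjusted p with the same CPM minimum, and the overlap of the groups was then not a criterion. The rule then added up to 3 members per list past the threshold and, for inflammasome, cytokine, macrophage and adipocyte lists, the 2 members with the smallest unadjusted p where none passed.

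The alternatives were DESeq2 size factors, upper quartile and total count scaling, the DESeq2 1.42.0 Wald test, limma-voom with and without library quality weights, no filter on low counts, a stricter filter of 1 CPM in at least 4 libraries, robust dispersion, each library left out in turn, a replicate block on the 6 libraries with shared numbers and the same 6 libraries without it, 1 surrogate variable from sva 3.50.0, an adjusted p of 0.10, a minimum fold of 1.5, and lists without members shared by several lists. A fit without the libraries labelled KO 4 and KO 5 was added after the data were seen.

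The test was tried on simulated counts for the same genes, means and library sizes, in which 200 genes were changed. For KO against WT, with 15959 simulated genes passing the filter, 6% of 50 genes changed 1.5-fold were recovered, 42% of those changed 2-fold, 74% of those changed 3-fold and 82% of those changed 4-fold, with 4 false calls among 106. Simulated lists of 20 independent genes gave 0 calls among 40 unshifted lists, and a list shifted by 0.5 log2 units was called. Real genes are correlated, within a list and beyond it, which both simulations leave out. The recovered shares may therefore not hold for the real libraries. Pseudogenes were matched to parent genes with blastn 2.17.0 on GENCODE M21 transcripts, at no less than 95% identity over at least 80% of the pseudogene. All groupings of the 8 libraries into 4 and 4 were refitted, 35 in number.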

Results

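Transcript abundance was measured in epididymal white adipose tissue, the visceral fat depot that lies beside the testis of mice aged 105 weeks. The deposited table held 8 libraries, of which 4 were labelled wild type (WT 2, WT 3, WT 5 and WT 6) and 4 were labelled as a knockout of Fmo3 in adipocytes (KO 3, KO 4, KO 5 and KO 6). Fmo3 encodes flavin-containing monooxygenase 3, which oxidizes trimethylamine to trimethylamine N-oxide. The counts per library summed to between 17531632 (KO 4) and 18485177 (WT 3), and 3 counts, taken as the detection floor, corresponded to 0.161 to 0.176 CPM (counts scaled by depth and TMM factor, as for all CPM below). Such floors cover counting error only. The labels do not say whether each library came from a separate animal, and the p-values therefore measure the spread between these libraries. All pairs of libraries differed by more than sampling noise, with a chi-square per gene between 18.6 and 119. The library labelled KO 3 lay farthest from the others on the first principal component, which held 32.7% of the variance, at −65.1, and WT 5 lay at the other end at 39.3.

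The first comparison asked whether the targeted gene was lower in the libraries labelled KO. This checks the labels only in part, because they name a knockout in adipocytes and the RNA is of whole tissue. Fmo3 (ENSMUSG00000026691, on chromosome 1) was low in the libraries labelled KO 3 and KO 6, at 0.941 and 0.792 CPM (16 and 14 counts), and high in those labelled KO 4 and KO 5, at 16.2 and 15.7 CPM (297 and 281 counts). In WT 2, WT 3, WT 5 and WT 6 it was 1.23, 1.77, 4.2 and 4.31 CPM. Fmo3 in KO 4 and KO 5 was thus above every WT library, whereas KO 3 and KO 6 were below every WT library. A loss in adipocytes alone would not raise Fmo3, but whole tissue cannot show whether the adipocytes of KO 4 and KO 5 kept the gene. The group means were 8.41 ± 8.71 CPM in the libraries labelled KO and 2.88 ± 1.61 CPM in WT (SD, n = 4 each). The log2 fold change was 1.55 with a standard error of 0.93, and it did not pass the test (adjusted p = 0.9998, edgeR quasi-likelihood). An exact two-sided permutation test of the 70 assignments gave p = 0.657, where the smallest possible value is 0.0286. The fold change was 0.60 with limma-voom and 0.56 with library quality weights, 1.0 without KO 4, −0.39 with a replicate block on the 6 libraries with shared numbers (0.76 in the same 6 without it), and −1.73 without KO 4 and KO 5, a setting chosen after the values were seen. Counts per gene carry no exon resolution, so that transcript lacking a deleted part of the gene could not be told from intact transcript. Because of these values, every direction below refers to how the libraries were labelled.

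The other flavin-containing monooxygenases, enzymes that oxidize nitrogen- and sulfur-containing compounds, did not pass the test in either direction. Fmo1 was at 165 ± 12.1 CPM in the libraries labelled KO and 171 ± 29.0 CPM in WT (SD, n = 4 each), and Fmo5 was at 68.6 ± 2.70 and 71.7 ± 17.6 CPM. Fmo2 was at 209 ± 119 and 165 ± 78.4 CPM. It too was highest in the libraries labelled KO 4 (324 CPM) and KO 5 (289 CPM) and lowest in KO 3 (70.6 CPM), and its log2 fold change of 0.34 was 0.04 without KO 4, 0.13 without WT 2, 0.18 without WT 3, 0.14 without KO 5, 0.62 without WT 5, 0.61 without KO 3 and 0.54 with library quality weights. It turned to −0.30 under the replicate block and −0.16 in the same 6 libraries without it, and to −0.58 without KO 4 and KO 5. Fmo4 was at 2.66 ± 0.886 and 2.11 ± 0.425 CPM (log2 fold change 0.33, 0.07 without KO 3, 0.20 without WT 5, 0.12 with library quality weights, 0.22 with a surrogate variable, 0.54 under the block and 0.56 in the same 6 libraries without it). Fmo1 and Fmo5, both near 0, changed direction in several settings. Fmo6 had 9 counts over all 8 libraries and Fmo9 had 0, so neither was tested. A count of 0 allows up to 3 counts, or at most 0.176 CPM (in KO 3).

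**Figure D1:**
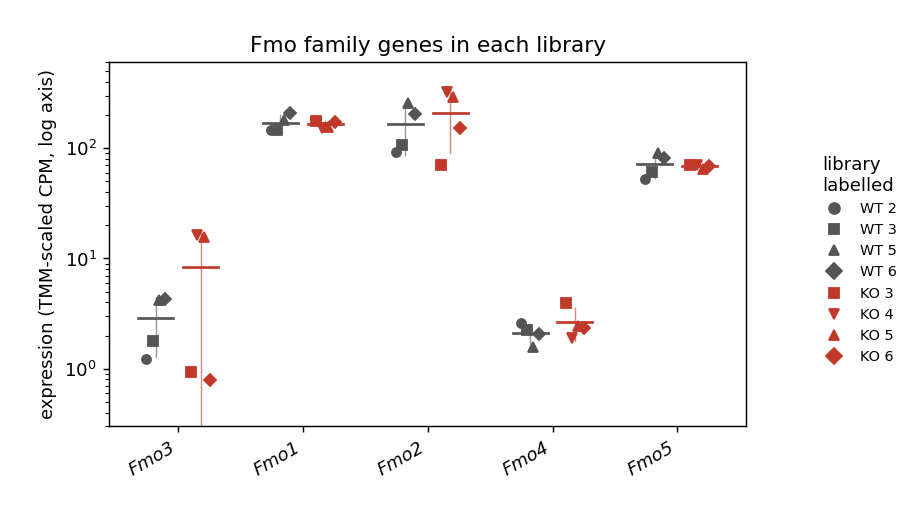
Expression of the 5 tested Fmo genes (TMM-scaled CPM, log axis) in each library, grey for WT and red for the libraries labelled KO, with the mean as a horizontal bar and the SD as a vertical line that ends at the axis where mean minus SD is below it. For Fmo3 the libraries labelled KO 4 (16.2 CPM) and KO 5 (15.7 CPM) lie above all WT libraries, and KO 3 (0.941 CPM) and KO 6 (0.792 CPM) below them.

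The next comparison asked which genes differed between aged fat labelled as lacking adipocyte Fmo3 and aged wild-type fat. Of 16182 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.185. At an unadjusted p under 0.05 there were 336 genes, 186 higher and 150 lower in the libraries labelled KO, against 809.1 expected by chance. DESeq2 called 5 genes and limma-voom 0. In 224 genes (1.38%) the groups did not overlap, against 2.86% expected by chance. The following genes, which did not pass, are those with the smallest unadjusted p among named genes of at least 2 CPM.

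On the higher side, Zfp949 (ENSMUSG00000032425), a zinc finger protein gene, had the smallest p of all genes tested. Its expression was 46.5 ± 13 CPM in the libraries labelled KO and 15.9 ± 2.05 CPM in WT (SD, n = 4 each), a log2 fold change of 1.55 with a standard error of 0.20, and every library labelled KO, KO 4 and KO 5 included, was above every WT library. DESeq2 gave it an adjusted p of 3.85e-08, and edgeR without a filter on low counts 0.0355, against 0.185 in the main test and 3.85e-08 to 1 over all alternatives. Arrdc3, an alpha-arrestin gene linked to adrenergic receptor trafficking, was at 157 ± 31.7 and 84.0 ± 15.3 CPM (log2 fold change 0.90, DESeq2 adjusted p = 0.0222, range over all alternatives 0.0222 to 1). Rgs1, a regulator of G-protein signalling in leukocytes, was at 8.78 ± 6.15 and 2.27 ± 0.357 CPM, and Srgap1, a GTPase-activating protein of the Slit-Robo pathway, at 18.5 ± 1.26 and 12.8 ± 1.37 CPM. Morf4l1-ps1, a processed pseudogene whose reads cannot be separated with certainty from those of Morf4l1, was at 3.17 ± 0.802 and 1.38 ± 0.0798 CPM.

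On the lower side, Ighg2b, an immunoglobulin heavy-chain constant gene, was at 8.06 ± 4.75 CPM in the libraries labelled KO and 39.3 ± 23.2 CPM in WT (log2 fold change −2.29, DESeq2 adjusted p = 0.0222, range over all alternatives 0.0222 to 1), with overlapping groups. Aplnr, the apelin receptor, was at 5.64 ± 2.20 and 15.3 ± 5.18 CPM, and Itih4, an acute-phase plasma protein gene, at 1.40 ± 0.526 and 3.39 ± 0.603 CPM. Bcl2a1d, an anti-apoptotic gene with near-identical copies that can share its reads, was at 1.45 ± 0.362 and 3.28 ± 0.671 CPM. Arrdc4, another alpha-arrestin gene, was at 28.1 ± 2.28 and 38.9 ± 2.48 CPM. The gene models Gm7049 and Gm11868, named here after their values were seen because DESeq2 called them, were at 11.5 ± 5.18 against 1.56 ± 0.345 CPM and at 1.96 ± 0.661 against 0.269 ± 0.132 CPM. Both are close copies of other genes, so their counts are uncertain. Gm7049 was also the 1 gene that edgeR called without KO 4.

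**Figure D2:**
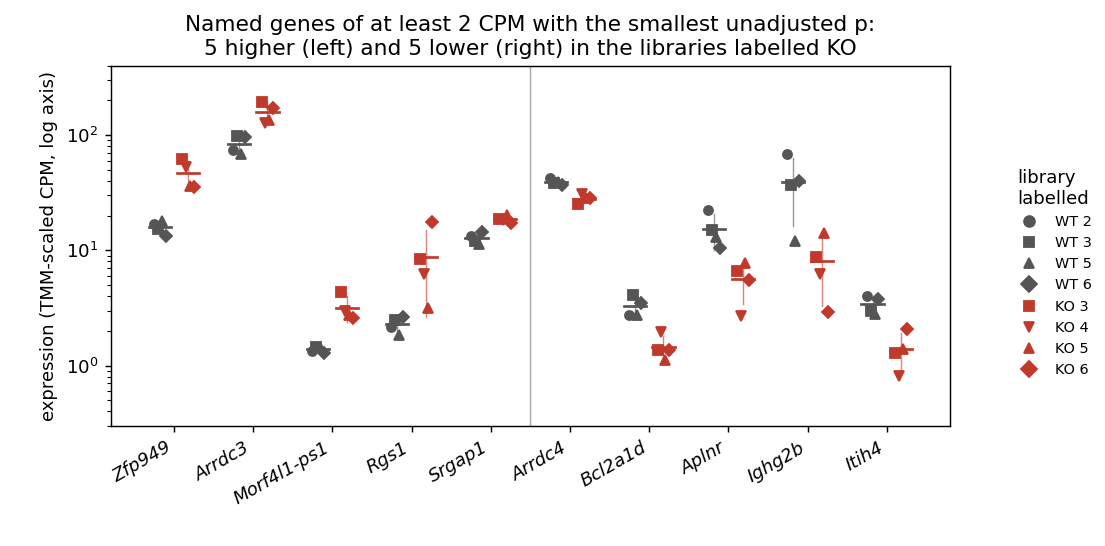
Expression (TMM-scaled CPM, log axis) of the 5 genes per direction with the smallest unadjusted p among those with an approved symbol and at least 2 CPM on average, grey for WT and red for the libraries labelled KO, with the mean as a horizontal bar and the SD as a vertical line. The groups do not overlap for 9 of these genes, Ighg2b being the exception, and 0 of the 10 passed the adjusted threshold of edgeR.

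Gene lists fixed beforehand were then compared, and 15 of 41 passed camera with its preset correlation of 0.01, 10 higher and 5 lower in the libraries labelled KO. With a correlation estimated from the libraries, 0 of the 41 passed, and the smallest adjusted p was 0.41. The rotation test fry likewise passed 0, with a smallest adjusted p of 0.828. No list member passed the adjustment over all genes. Of the 15 lists, 2 held members that passed when adjusted over the list alone. That adjustment does not allow for the 41 lists tested, so these members are not called changed. The members named below are given as values. Those of the inflammasome, cytokine, macrophage and mature adipocyte lists follow the rule fixed beforehand, and the others were chosen after the values were seen, from the small unadjusted p in their list.

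Antigen presentation and lymphocyte genes were lower on average, in calls that were not kept with an estimated correlation. Of 15 genes of MHC class II and dendritic cells, which present peptides to helper T cells, 13 were lower, with a mean log2 fold change of −0.55 (camera adjusted p = 2.02e-12, and adjusted p = 0.41 with an estimated correlation). Adjusted over the list alone, 4 members passed and 0 did over all genes. H2-Aa was at 417 ± 30.6 CPM in the libraries labelled KO and 659 ± 187 CPM in WT (SD, n = 4 each), and Ciita, the master regulator of MHC class II transcription, at 11.6 ± 4.01 and 22.7 ± 7.96 CPM. H2-DMa and H2-DMb1, which load peptide onto these molecules, were at 32.5 ± 5.08 against 50.2 ± 13.4 CPM and 26.8 ± 3.81 against 40.3 ± 10.7 CPM. Among B and plasma cell markers 19 of 21 were lower, with a mean of −0.98 (camera adjusted p = 2.02e-12, and adjusted p = 0.424 with an estimated correlation), and 3 passed when adjusted over the list alone. These were Ighg2b, Iglc2 (16 ± 5.15 against 41.3 ± 18.0 CPM) and Ighd (4.19 ± 2.11 against 17.1 ± 11.2 CPM), immunoglobulin genes whose reads can be shared with related segments. T and NK cell markers were lower in 19 of 24 members, with a mean of −0.37 (camera adjusted p = 0.00041, and adjusted p = 0.672 with an estimated correlation), and 0 passed when adjusted over the list alone. The library WT 3 was the highest for all these lists. Without it the mean was −0.26 for B and plasma cells, and −0.02 for T and NK cells, which no longer passed (camera adjusted p = 0.65). T and NK cells also did not pass without KO 4 and KO 5 (−0.34, adjusted p = 0.146).

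Lipid-associated macrophage genes, which mark macrophages that take up lipid from adipocytes, were higher in 18 of 19 members, with a mean log2 fold change of 0.57 (camera adjusted p = 8.4e-08, and adjusted p = 0.496 with an estimated correlation). None of them passed when adjusted over the list alone. Gpnmb was at 135 ± 93.1 CPM in the libraries labelled KO and 51.5 ± 15.7 CPM in WT (SD, n = 4 each), Mmp12 at 41.3 ± 24.3 and 13.7 ± 5.38 CPM, and Atp6v0d2, a lysosomal proton pump subunit, at 15.7 ± 11.5 and 4.31 ± 2.34 CPM. The list mean was 0.34 without KO 6, the highest library for this list. KO 5 was the lowest, at −0.475 relative to the mean of the 8 libraries, below every WT library (−0.387 to −0.0599). General macrophage markers did not pass, with 9 of 20 higher and a mean of −0.09 (camera adjusted p = 0.416). Among them Marco, a scavenger receptor, was at 3.42 ± 3.53 and 21.3 ± 21.3 CPM, and Lyve1, a marker of perivascular resident macrophages, at 198 ± 138 and 105 ± 11.1 CPM. Single libraries weighed on both: Marco was at 50.8 CPM in WT 3 and 8.72 CPM in KO 5, and its log2 fold change of −2.63 was −1.73 without WT 3 and −1.55 under the replicate block, while that of Lyve1 went from 0.91 to 0.49 without KO 5, 0.41 with limma-voom and 0.44 under the block. Haemoglobin and other erythroid genes were higher in 7 of 7 members, with a mean of 1.51 (camera adjusted p = 0.000252, and adjusted p = 0.672 with an estimated correlation). The library labelled KO 6 had the highest erythroid level, 2.56 log2 units above the mean of the 8 libraries, and KO 5 the lowest at −1.53. Without KO 6 the erythroid mean was 0.43 and no longer passed (camera adjusted p = 0.487). It was 0.71 with limma-voom and 2.34 without KO 4 and KO 5.

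Genes of lipid synthesis and mitochondrial metabolism were higher on average by small amounts, and none of the 6 lists in this paragraph passed with an estimated correlation. De novo lipogenesis genes were higher in 17 of 18 members, with a mean log2 fold change of 0.39 (camera adjusted p = 0.000166, and adjusted p = 0.672 with an estimated correlation), and Acaca, the acetyl-CoA carboxylase that starts fatty acid synthesis, was at 561 ± 256 CPM in the libraries labelled KO and 350 ± 102 CPM in WT (SD, n = 4 each). The 13 protein-coding genes of the mitochondrial genome were all higher, with a mean of 0.27 (camera adjusted p = 5.25e-05, and adjusted p = 0.672 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 21 members (mean 0.19, camera adjusted p = 0.00041, and adjusted p = 0.672 with an estimated correlation), among them Insig1, a sterol sensor of the endoplasmic reticulum, at 116 ± 29.6 and 81.5 ± 4.42 CPM. Thermogenic and beige fat genes were higher in 13 of 17 members (mean 0.22, camera adjusted p = 0.00462), citrate cycle and branched-chain amino acid genes in 26 of 30 (mean 0.10, camera adjusted p = 0.0166), and lipolysis and triglyceride genes in 17 of 22 (mean 0.16, camera adjusted p = 0.0166). With an estimated correlation the adjusted p of these lists was 0.424, 0.672 and 0.672. In the last list Lpin1, a phosphatidate phosphatase, was at 520 ± 124 and 333 ± 93.8 CPM. Of all members of the 6 lists, 0 passed when adjusted over the list alone. KO 3 had the highest mature adipocyte marker level of the 8 libraries. Without KO 3 the mean was −0.05 for lipolysis, 0.02 for the citrate cycle, 0.25 for lipogenesis and 0.19 for thermogenic genes, and none of these 4 lists passed. Lipogenesis also lost its call without WT 5 (mean 0.23) or KO 5 (0.25) and was at 0.59 without KO 4. The citrate cycle list lost it without WT 2 (0.086), WT 3 (0.089), WT 5 (0.072) or KO 6 (0.044) and was at 0.17 without KO 4. The lipolysis list lost it without WT 5 (0.063) or KO 6 (0.15) and was at 0.27 without KO 4, and the thermogenic list lost it without KO 6 (0.15). Cholesterol synthesis had a mean of 0.13 without KO 3 and of 0.11 without KO 5, where it no longer passed. With library quality weights the call also ended for cholesterol synthesis (0.08), lipogenesis (0.20) and lipolysis (0.07), with a surrogate variable for lipolysis (0.05) and the citrate cycle (0.06), and for lipolysis with limma-voom (0.11) and with members shared between lists left out (0.14). The mitochondrial list had a mean of 0.15 without KO 6.

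Clock genes, which follow the time of day, were higher in 14 of 18 members, with a mean log2 fold change of 0.20 (camera adjusted p = 0.000166, and adjusted p = 0.41 with an estimated correlation). Per1, a core clock repressor, was at 177 ± 46.1 CPM in the libraries labelled KO and 119 ± 16.5 CPM in WT (SD, n = 4 each), and Cry2, another repressor, at 90.5 ± 21.2 and 66.8 ± 9.35 CPM. Extracellular matrix genes were higher in 23 of 28 members, with a mean of 0.20 (camera adjusted p = 0.00182, and adjusted p = 0.672 with an estimated correlation). Postn, a matrix protein of remodelling tissue, was at 149 ± 50.1 and 92.6 ± 28.3 CPM. Without KO 5 the matrix mean was −0.01, without KO 4 and KO 5 it was −0.12, neither passing, and without KO 3 it was 0.32. Cytosolic ribosomal protein genes were lower in 34 of 34 members, with a mean of −0.17 (camera adjusted p = 1.31e-06, and adjusted p = 0.672 with an estimated correlation). This list no longer passed without WT 5 (mean −0.05), without KO 5 (mean −0.08) or without KO 4 and KO 5 (−0.09), and its mean was −0.26 without WT 6. None of the members of these 3 lists passed when adjusted over the list alone.

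The title of the series names inflammasome activation and adipose tissue dysfunction, and lists for both were therefore fixed as main results. The lists measure transcript abundance only and do not test inflammasome activation at the protein level. Inflammasome and pyroptosis genes did not pass, with 8 of 20 higher, a mean log2 fold change of −0.10 and 0 members past the threshold when adjusted over the list alone (camera adjusted p = 0.113, and adjusted p = 0.672 with an estimated correlation). Il1rn, the antagonist of the interleukin-1 receptor, was at 3.99 ± 1.66 CPM in the libraries labelled KO and 1.91 ± 0.320 CPM in WT (SD, n = 4 each), and Pycard, the adaptor that recruits caspase-1, at 8.12 ± 3.37 and 12.5 ± 3.48 CPM (log2 fold change −0.62, −0.94 without KO 4 and −0.96 in the 6 libraries with shared numbers). The mean ranged from −0.22 without KO 4 to 0.01 without KO 3, and passed camera without WT 5 (−0.16), WT 6 (−0.16), KO 4 or KO 6 (−0.19). It was −0.03 without WT 2 and −0.05 without WT 3. Mature adipocyte genes did not pass either, with 19 of 25 higher and a mean of 0.11 (camera adjusted p = 0.0542, and adjusted p = 0.672 with an estimated correlation). Cidec, a lipid droplet protein, was at 2840 ± 535 and 2307 ± 129 CPM, and Acsl1, an acyl-CoA synthetase, at 1503 ± 503 and 1154 ± 289 CPM. Their log2 fold changes of 0.30 and 0.38 were 0.17 for Cidec without KO 3 and 0.16 for Acsl1 without KO 6. The mean ranged from −0.03 without KO 3 to 0.19 without KO 4. It passed without WT 6 (0.18), KO 4 or KO 5 (0.13), and was 0.06 without WT 5. Cytokine and chemokine genes were higher in 11 of 22 members (mean −0.26, camera adjusted p = 0.141). The B cell chemoattractant Cxcl13 was at 46.5 ± 20.9 and 345 ± 338 CPM (log2 fold change −2.89, −1.57 with limma-voom and −0.63 under the replicate block), and Il10 at 0.981 ± 0.376 and 1.97 ± 1.25 CPM (log2 fold change −1.0, and −0.58 without WT 3).

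**Figure D3:**
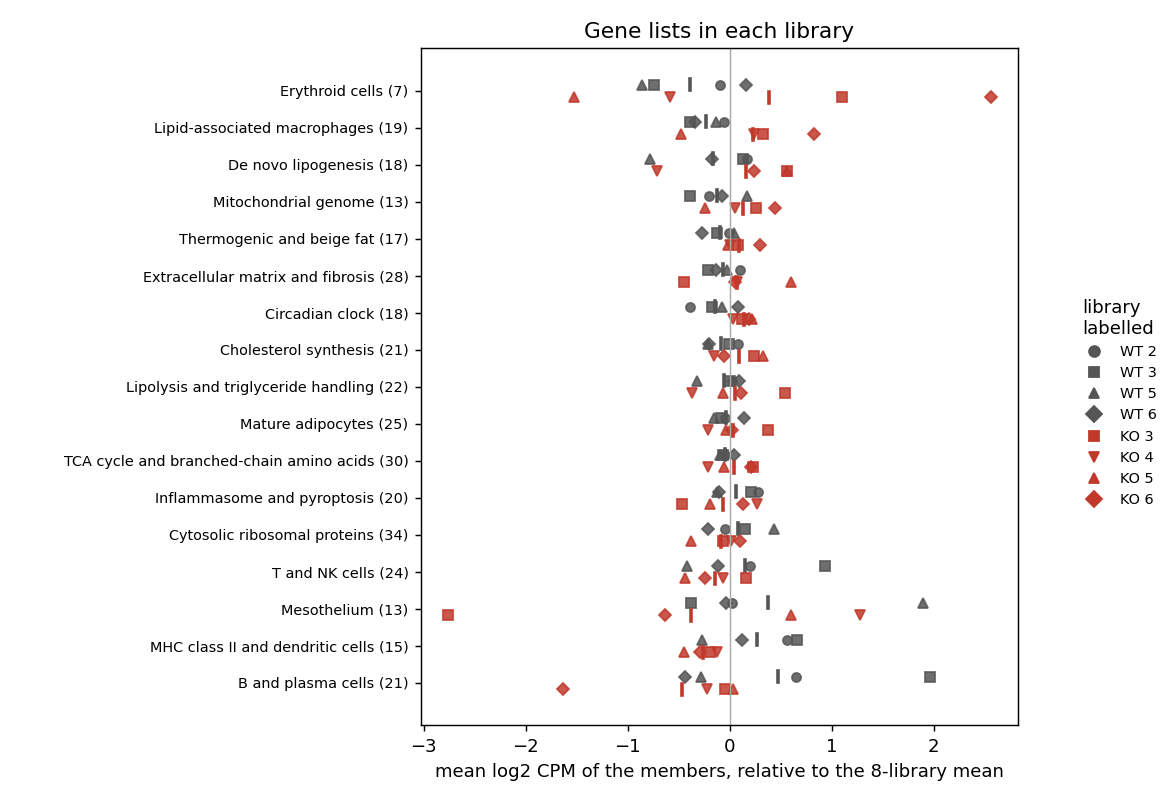
Mean log2 CPM of each list's members in each library, relative to the mean of the 8 libraries, for the 15 lists that passed camera with the preset correlation and the inflammasome and mature adipocyte lists, which did not. Grey marks WT and red the libraries labelled KO, vertical bars are group means, and the number of members tested follows each name. The groups overlap in all 17 lists shown, with KO 3 lowest for mesothelium at −2.76 and KO 6 highest for erythroid genes at 2.56.

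Markers of neighbouring tissues differed between single libraries. Mesothelial genes, from the cell layer that covers visceral fat, were lower in 13 of 13 members, with a mean log2 fold change of −0.43 (camera adjusted p = 0.00189, and adjusted p = 0.672 with an estimated correlation). The list lay at −2.76 in the library labelled KO 3 and at 1.90 in WT 5, relative to the mean of the 8 libraries. Without WT 5 its mean turned to 0.39, and without KO 3 it was −0.07, in neither case passing camera. The call also ended with DESeq2 (−0.44, adjusted p = 0.0588) and with library quality weights (−0.44, adjusted p = 0.0683), at about the same mean. It was −0.66 without WT 3, −1.02 without KO 4 and −0.26 without KO 6. Upk3b, a mesothelial membrane protein gene, was at 166 ± 148 CPM in the libraries labelled KO and 249 ± 186 CPM in WT (SD, n = 4 each). Of the 32 genes of the epididymis and testis list fewer than 5 passed the count filter, and the list was not tested. Leaving out Lcn2, which inflamed fat also expresses, the remaining 31 genes had 350 counts in KO 5 and 291 in WT 5, against 8 to 51 in each of the other 6 libraries. In KO 5 the sperm protamine Prm2 accounted for 131 of these counts, and in WT 5 the seminal vesicle gene Svs5 for 72. Fibroblast and progenitor markers (mean −0.04, camera adjusted p = 0.743), endothelial markers (0.18, adjusted p = 0.377) and smooth muscle and pericyte markers (0.01, adjusted p = 0.808) did not pass. KO 3 was the lowest of the 8 libraries for fibroblast markers, at −0.80, and KO 4 for endothelial markers, at −1.18.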

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

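In this part, the tests chosen only after the result was seen were the chromosomal neighbours and extra copies near Zfp949, the labels and stromal markers for Fmo3, and the dendritic cell markers. Within groups of 4 libraries, 82 sets of values were examined for a library far from the others. There were 2 such cases, where chance gives about 1 in 20 (4.1 expected). Marco was far higher in KO 5 than in the other libraries labelled KO, the gap being 0.923 of the group's range, at 8.72 CPM against 1.53 to 1.75 CPM. The B and plasma cell list was far lower in KO 6, the gap being 0.852 of the range.

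The real split gave 0 genes past the threshold, so that 35 of the 35 splits of the libraries necessarily gave as many and their number tells nothing, and the highest of the other splits gave 1. At an unadjusted p under 0.05, 28 of the 35 gave as many genes as the real split, which fits chance. The split of WT 2, WT 3, KO 3 and KO 6 against the rest gave 3222 genes at an unadjusted p under 0.05, against 336 for the real one, but 0 past the adjusted threshold. It was picked as the highest of the other splits, and no chance value for that highest count was computed, so it decides nothing. That split also separates the 4 lowest from the 4 highest Fmo3 values. It is not particular to Fmo3. It divides the libraries below 0 on the first principal component (−65.1 to −8.87) from those above 0 (9.93 to 39.3). The fibroblast and progenitor list means, which include Fmo2, are separated by it too (−0.80 to 0.02 against 0.17 to 0.45). For gene lists, 18 of the 35 splits gave as many past camera's preset threshold as the 15 of the real split, and the highest other gave 27, so chance was not excluded for the number of lists.

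Fmo3 lay above every WT library in KO 4 and KO 5. A wrong label of these libraries was examined with the 10 genes that differed most between KO 3 and KO 6 and the WT libraries. Both KO 4 and KO 5 lay beyond every WT library on the KO side for 3 of the 10, among them Zfp949 and Gm7049. For Zfp949 the gap was wide, at 52.3 CPM in KO 4 and 36.2 CPM in KO 5 against 13.4 to 18.1 CPM in WT. Gm7049 is a close copy of Me1, which lies near Zfp949, so it and Zfp949 may not be independent. Chance gives 0.67 for genes chosen without regard to the WT libraries. These 10 were chosen with the same WT libraries, which can raise that number, so the 3 cannot be weighed against it. Both lay on the WT side of the midpoint for 7, which the choice of genes favours even with right labels. A wrong label therefore stays open. WT libraries in their place would not by themselves explain Fmo3 at 16.2 and 15.7 CPM, above the WT maximum of 4.31 CPM. The midpoint criterion was written first and set aside because of that choice of genes. RNA from stromal cells that keep the gene may contribute. WT 5 goes the other way, as its Fmo3 was at 4.2 CPM, against 16.2 in KO 4 and 15.7 in KO 5. Yet it had the highest fibroblast and progenitor list mean of the 8 libraries (0.453, against 0.381 and 0.241). Its mesothelial mean was the highest too (1.90, against 1.28 and 0.605). These means are of the full lists, whereas the relations below left Fmo2 out of the fibroblast and progenitor markers (16 members). Over the 8 libraries Fmo3 went with the fibroblast and progenitor marker mean at Pearson r = 0.652 (exact permutation p = 0.0735, adjusted 0.11 over 3 relations) and Spearman rho = 0.69 (exact permutation p = 0.0694, adjusted 0.104), and at r = 0.671 without KO 3 and WT 3, so this was not decided. For mesothelial markers r was 0.678 (exact permutation p = 0.0596, adjusted 0.11) and rho 0.738 (p = 0.0458, adjusted 0.104), with r = 0.895 without KO 3 and WT 5, and for mature adipocytes r was −0.518 (exact permutation p = 0.187) and rho −0.50 (p = 0.216), with r = −0.608 without KO 3 and WT 6. A transcript that outlasts a deletion of part of the gene, and the knockout itself, were not tested.

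Zfp949 had neighbours on chromosome 9 that were lower in the libraries labelled KO. Of the 10 tested genes on either side (order of GRCm38), 5 had an unadjusted p under 0.05, a count that 0.189% of all such neighbourhoods reached. The highest elsewhere was 6, and 144 of 1000 shuffles of the gene order held a window as high. The window was centred on the gene with the smallest p of all, so the 0.189% is not a test. The shuffles, which allow for the choice of a window, leave chance open. The 4 genes next to it on one side, 9430037G07Rik (log2 fold change −0.99), Mthfsl (−0.55), Bcl2a1d (−1.18) and 9330159M07Rik (−0.79), lay below every WT library in all libraries labelled KO. This is consistent with a linked segment that differs between the groups, for example from another strain around a transgene. Extra copies of the segment would raise all of these genes by about the log2 fold change of Zfp949, 1.55, whereas the 20 neighbours had a mean of −0.14 (SD 0.48 over genes) and 9 were above 0, none by more than 0.60. Extra copies that reach over the neighbours are thus argued against, and copies of Zfp949 alone stay open. This criterion replaced an earlier one on the 5 genes alone, which had been picked for the pattern. Pseudogene reads stay open: Gm7049 (98.4% identical to Me1), Gm11868 (98.0% to Cyb5r4) and Morf4l1-ps1 (99.8% to Morf4l1) have parents among the 25 tested genes on either side of Zfp949, but 0 other tested pseudogenes do, so the prediction could not be tested on genes that had not raised it. With those 3 included, 3 of 3 against 3 of 291 others had an unadjusted p under 0.05. The log2 fold changes of Gm7049, Gm11868 and Morf4l1-ps1 were 2.88, 2.84 and 1.19. Their parents Me1, Cyb5r4 and Morf4l1 were at 0.24, −0.36 and −0.16. More parent transcript alone would thus not account for the 3 pseudogenes, whereas a changed assignment of reads stays open.

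MHC class II genes were lower on average in the libraries labelled KO, but whether they differ is itself not settled. Their list passed camera with the preset correlation only (adjusted p = 0.41 with an estimated correlation and 0.828 with fry), 0 members passed over all genes, and WT 5, at −0.272 relative to the mean of the 8 libraries, lay within the range of the libraries labelled KO (−0.449 to −0.126). The 7 pathway genes had a mean log2 fold change of −0.73, with an SD of 0.129 over genes. With the B cell marker mean as a covariate it was −0.384, with a standard error of 0.0553 over the 7 genes. It lay within that error of the limit of −0.36 set beforehand (0.5 times the mean without the covariate), so fewer B cells may account for a part of unknown size. The limit alone was met, which would have argued against fewer B cells as the main cause, and the margin of 1 standard error was added after this value was seen. Fewer dendritic cells could not be told apart from a change within cells: 7 dendritic cell markers had a mean of −0.294 with a standard error of 0.12 over the markers, against the same limit of −0.36. Both standard errors treat genes that can move together as separate values. They do not measure the spread between the 8 libraries, so neither comparison with the limit decides. A difference through the genotype stays open and was not tested apart from the labels.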

How the results depend on the processing

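The fit without KO 4 and KO 5 was chosen after the data were seen. Of 23 alternatives for the count of changed genes, 20 gave 0. The DESeq2 Wald test gave 5 (4 higher, 1 lower) and edgeR without a filter on low counts 2 (both higher), and leaving out each library in turn gave 0 to 1, the 1 gene being Gm7049, higher without KO 4. The cause was not tested. Among 462 values of the 22 named genes other than Fmo3, 449 kept direction and side of the threshold, 4 passed it and 9 reversed. None of the 22 passed in the main test, so keeping the side means not passing. Most were picked by a small unadjusted p in these libraries, which favours a kept direction. The size could still move, as for Cxcl13 from −2.89 to −0.63 under the block. Of the 15 passing lists, 5 (MHC class II, B and plasma cells, lipid-associated macrophages, mitochondrial genome and clock) passed in every setting except the estimated correlation and fry, which gave 0 lists. The settings they passed share the preset correlation of 0.01, whereas the estimates were 0.365, 0.448, 0.361, 0.709 and 0.0635 in that order. An exact permutation test of each list mean over the libraries gave p = 0.0857, 0.286, 0.171, 0.229 and 0.0571, so these calls are not secured at the level of libraries. Leaving out each library gave 12 to 26 lists, the replicate block 23 and the same 6 libraries without it 21. Fmo3 ranged from 1.0 to 1.92 with each library left out, was 0.60 with limma-voom, 0.56 with library quality weights and 0.76 in the 6 libraries with shared numbers, and reversed to −0.39 under the block and to −1.73 without KO 4 and KO 5, the latter by construction. Inflammasome genes ranged from −0.22 to 0.011 with each library left out, and mature adipocytes from −0.031 to 0.19. These lists gained a call at −0.17 and 0.14 under the block, −0.14 and 0.18 in the same 6 libraries without it, and −0.24 and 0.23 without KO 4 and KO 5, and adipocytes at 0.11 with DESeq2. With each library left out, Fmo5 ranged from −0.20 to 0.057, Fmo1 from −0.12 to 0.06, mesothelium from −1.02 to 0.39, lipolysis from −0.046 to 0.27 and extracellular matrix from −0.0065 to 0.32. With library quality weights Fmo5 was 0.12 and Fmo1 0.070. Fmo2 was −0.30 under the block, −0.16 in the same 6 libraries and −0.58 without KO 4 and KO 5, where Fmo1 was 0.035 and extracellular matrix −0.12. Whether the replicate numbers pair the libraries was not settled. Same-numbered deviations correlated at 0.374, 0.061 and 0.167 for numbers 3, 5 and 6. WT 3 and KO 3 were each other's best match, as were WT 6 and KO 6, whereas WT 5 matched KO 4 best and KO 5 matched WT 6 best. Yet WT 5 and KO 5 held the most epididymis and testis counts (291 and 350, Lcn2 left out). The block gave 0 genes. The median log2 fold change of all genes was 0.01 with TMM and lay between −0.03 and 0.00 with the other scalings. In simulations at this depth and number of libraries, 6% of 1.5-fold changes were recovered, so changes of that size are mostly beyond reach. The simulated genes varied independently of each other, so recovery in the real libraries may differ.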

Other observations

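The neighbours of Adipoq were examined after their values were seen. Further lists, none of which passed camera, complete the description. Oxidative phosphorylation genes of the nucleus were higher in 49 of 56 members (mean log2 fold change 0.07, camera adjusted p = 0.0693), and fatty acid oxidation genes in 18 of 22 (0.06, adjusted p = 0.101). Among endoplasmic reticulum stress genes 17 of 25 were higher (0.10, adjusted p = 0.0546), with Chac1, a glutathione-degrading enzyme, at 17.9 ± 11.0 CPM in the libraries labelled KO and 7.76 ± 1.75 CPM in WT (SD, n = 4 each). Interferon-stimulated genes (−0.12, adjusted p = 0.0546), NF-kB pathway genes (−0.16, adjusted p = 0.0542), proliferation genes (−0.25, adjusted p = 0.0693), early response genes (−0.10, adjusted p = 0.0997) and replication-dependent histones (−0.12, adjusted p = 0.123) had means below 0. Egr3, an early response transcription factor, was at 1.87 ± 0.660 and 4.34 ± 1.44 CPM. Neutrophil and mast cell markers had a mean of 0.36 (adjusted p = 0.0542).

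Senescence factors (0.18, camera adjusted p = 0.273), autophagy and lysosome genes (0.05, adjusted p = 0.202), insulin and glucose genes (0.05, adjusted p = 0.232), antioxidant genes (0.03, adjusted p = 0.743) and genes of choline and one-carbon metabolism (0.03, adjusted p = 0.743), lay near 0 or varied between members. Skeletal muscle genes (0.13, adjusted p = 0.56) and the Fmo family as a list (0.42, adjusted p = 0.377) did not pass. For Schwann cell genes the mean was 0.24 and the median −0.05, and camera's direction was down (adjusted p = 0.94). Genes next to Fmo3 on chromosome 1 had a mean of −0.21 (adjusted p = 0.56), and the list of Adipoq neighbours fixed beforehand −0.25 (adjusted p = 0.808).

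A knockout in adipocytes is often made with a Cre transgene driven by Adipoq sequence, though the labels do not name the driver. A large transgene of that kind may carry intact copies of the genes next to Adipoq, which would then be higher wherever the transgene is present. Of the 3 tested genes on either side of Adipoq, St6gal1 was near 0 (log2 fold change 0.01) and the other 5 were higher in the libraries labelled KO, B630019A10Rik alone with an unadjusted p under 0.05 (0.00326, the others 0.101 to 0.959), and the mean z of all 6 lay at the 99.95 percentile of 15856 such neighbourhoods. B630019A10Rik was the clearest, at a log2 fold change of 1.44 with a standard error of 0.371 and groups that did not overlap, and its reads can be shared with BC106179 beside it (0.38). Rfc4 (0.42), 6330408M09Rik (0.46) and Gm24616 (0.71) overlapped between groups, as did Eif4a2 farther out (0.45), while Kng1 (−1.12), Gm45338 (−0.65) and Masp1 (−0.07), also farther out, and Fetub (−1.04) of the wider list were below 0, and Adipoq itself (0.00) was near 0. The window was chosen on values already seen and the wider list fixed beforehand did not pass, so this remains a hypothesis that reads over the transgene would settle.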
